A study of Mus musculus with 22 samples.

How the data were processed

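The study profiled single nuclei of mouse cerebellum in 3 behavioural paradigms, and again after targeting of Fgfr2. Per the labels' protocols, nuclei were released by douncing, cleaned on an iodixanol gradient, and sorted as singlets and for GFP fluorescence to obtain Purkinje nuclei. Libraries were made with a droplet-based 3' kit, the Chromium Single Cell 3' V3 chemistry, per the labels' protocols. In this chemistry each droplet carries 1 barcode sequence, which marks the transcripts of the nucleus it captured. Per the submitters' processing notes the reads were processed with Cell Ranger on the mouse build mm10. The Cell Ranger version, the gene annotation, the use of intronic reads and the depth equalisation across aggregated libraries are not given in the sources used here.

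The values used here are text, as deposited by the authors. They consist of 3 lists of nucleus barcodes and 3 lists of genes, a barcode list and a gene list for each of 3 aggregated tables. Per the labels, 8 samples belong to the first table and 8 samples, marked as the second replicate, belong to the second table. The labels of 4 samples, which are scramble control and Fgfr2 knockout samples, name the knockout table, and those of 2 further knockout samples name no table. A barcode is a sequence of 16 bases followed by a library number, and 0 of the barcodes departed from this form. No expression values were analysed here. The depth of each library in reads or transcripts is therefore unknown, and the test of gene expression between conditions that had been planned was not run. No label ties a library number to a sample. Library numbers were not assigned to conditions by their order, so values are given for each library and as range and median, with no comparison between conditions.

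Nuclei per library were counted as the barcodes listed under each library number, that is, the barcodes that passed the authors' cell calling. No doublet caller was run here, since it needs expression values, and whether the authors removed doublets before these lists were made is not given in the sources used here. A listed barcode can therefore stand for a droplet that held more than 1 nucleus, which the sorting of singlets does not exclude. Barcode sequences were then compared between all 253 pairs of the 23 libraries. Independent libraries share some sequences by chance, since all draw from the same pool of barcode sequences. The size of that pool was estimated as the sum of the products of the paired library sizes divided by the sum of the shared sequences. The observed number for each pair was tested against the expected number with an exact Poisson test, two-sided, and adjusted by Benjamini-Hochberg over the 79 pairs within tables and over the 174 pairs across tables, at a threshold of 0.05. Intervals are exact and cover 95%, for counting error only. The procedure was tested on simulated data in 20 runs of 23 libraries of the observed sizes, drawn from a pool of 3400000 sequences. The estimates lay between 3326799 and 3470638, and 2 pairs were called over all runs without added sharing. After 200 sequences were copied from 1 library to the other in each of 3 pairs, all 60 such pairs were called, together with 12 others over all runs. The 2 and the 12 count calls above and below chance together. Smaller additions were not simulated, so the 60 calls say nothing of weaker sharing. The 3 pairs joined the same 3 libraries. The same 200 sequences were copied for 2 of the pairs, so they lay in all 3 libraries and the remaining pair gained more than 200.

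Genes were compared between tables by identifier. Identifiers were also matched to GENCODE release M21, an annotation of GRCm38, the assembly that mm10 denotes. The coordinates given are those of GENCODE M21, and the authors' own annotation release may have placed a gene's ends differently. Gene lists for cerebellar cell types, activity-induced genes, fibroblast growth factor receptor signalling and synaptic plasticity were fixed before the data were examined. The rule for named genes covered features present in only some tables, Fgfr2, and list members missing from a table; the example genes given for the lists were chosen outside it. Alternatives were fixed before the data were examined, except that the estimate of the pool without the pairs called above chance was chosen after seeing the data. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.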

Results

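Single-nucleus transcriptome libraries were made from mouse cerebellum to follow Purkinje neurons, the output neurons of the cerebellar cortex. The paradigms covered activity, motor learning and associative learning. The labels described 22 samples in 12 groups. Of these groups, 2 came from an activity paradigm (baseline and activity), 3 from a motor learning paradigm and 3 from an associative learning paradigm (baseline, learning and learned in each), all with 2 samples per group. The knockout experiment, which the labels place in motor learning, had baseline and learned groups only. It added 2 scramble control samples, 1 at each of these stages, and 4 Fgfr2 knockout samples, 2 at each. Fgfr2 encodes a receptor tyrosine kinase for fibroblast growth factors. The design sets each activity, learning or learned group against the baseline of its own paradigm, and sets the knockout against the scramble control. None of these contrasts could be evaluated from barcode and gene lists, because they hold no expression values and their library numbers are not tied to samples. The values that follow describe the nuclei recovered, the separation of the libraries and the genes that were open to measurement.

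Altogether 242953 nuclei were listed in 23 libraries. The first table held 74226 nuclei in 9 libraries, 1 more library than the 8 samples whose labels name that table. Its libraries ranged from 5409 to 13090 nuclei with a median of 8025. The second table, made from the second replicates, held 76251 nuclei in 8 libraries, with a range of 7517 to 11106 and a median of 9713. The knockout table held 92476 nuclei in 6 libraries, from 13878 to 16560 with a median of 15498. The labels of 4 samples name that table, and those of 2 further knockout samples name no table. Each library of the knockout table exceeded each library of the other tables. The ratio of the largest to the smallest library was 2.42 in the first table, 1.48 in the second table and 1.19 in the knockout table. Differences between tables were not tested, since the libraries of a table come from several conditions and are not replicates of a group.

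**Figure D1:**
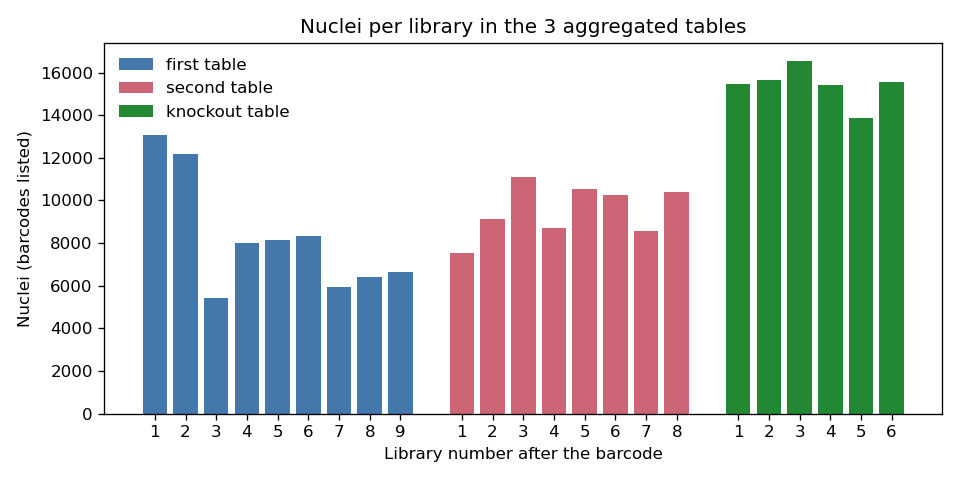
Nuclei listed in each library (bars, number of barcodes on the vertical axis, starting at 0) by library number, coloured by table. The 6 libraries of the knockout table hold 13878 to 16560 nuclei, above the highest library of the first table at 13090.

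Whether the libraries were distinct was examined through the barcode sequences they shared. Libraries 3, 4 and 5 of the second table shared many more sequences with each other than chance gives, and no other pair of libraries did. Libraries 3 and 4 shared 633 sequences where 32.0 were expected, a ratio of 19.8 (95% interval 18.2 to 21.4). Libraries 4 and 5 shared 627 against 30.4 expected, a ratio of 20.6 (95% interval 19.0 to 22.3). Libraries 3 and 5 shared 464 against 38.8 expected, a ratio of 11.97 (95% interval 10.9 to 13.1). The exact Poisson test returned p-values of 0 for these 3 pairs, too small for the calculation to resolve. These ratios depend on the pool, which here was estimated with the 3 pairs included. When it was estimated without them, the ratios in the same order were 24.0 (22.1 to 25.9), 25.0 (23.1 to 27.1) and 14.5 (13.2 to 15.9). When the pool was estimated within the second table alone, where these pairs weigh most, the ratios were 7.11, 7.43 and 4.31. All 3 pairs stayed above chance both ways. In these libraries 6.05% of the nuclei of library 3 (95% Clopper-Pearson interval 5.61 to 6.51), 9.59% of library 4 (8.98 to 10.2) and 6.32% of library 5 (5.87 to 6.81) carried a sequence also listed in another of the 3. Of the 29046 distinct sequences in these libraries, 425 were found in all 3 and 449 in exactly 2.

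The remaining 250 pairs shared between 6 and 82 sequences each. Their scatter around the number expected by chance was 0.905 times that of a Poisson distribution, with the expectation taken from those pairs alone (two-sided chi-square p = 0.285). The pool estimated from those pairs was 3663254 sequences (95% interval 3581730 to 3747106), against 3017703 (2957016 to 3079952) from all pairs. With the estimate from all pairs, 1 of the 79 pairs within tables and 1 of the 174 pairs across tables shared fewer sequences than chance by the exact Poisson test. Neither was called with the pool estimated without the 3 pairs above chance. Across tables, 0 pairs were above chance by the same test. With the estimate from all pairs, 30 of the 174 had an unadjusted p below 0.05, all of them sharing fewer sequences than expected. With the pool estimated without the 3 pairs above chance, 5 of the 174 did, of which 3 shared more than expected, and the lowest adjusted p was 0.638 by the exact Poisson test. The highest share of a smaller library's sequences found in a library of another table was 0.581%.

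**Figure D2:**
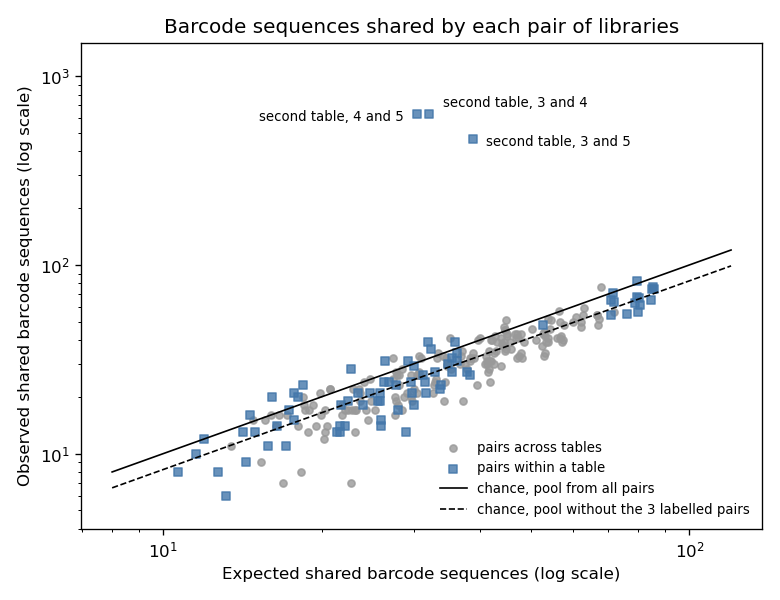
Observed against expected number of shared barcode sequences for the 253 pairs of libraries (points; both axes logarithmic), with pairs within a table as squares and pairs across tables as circles. The solid line marks equality with chance for the pool of 3017703 sequences and the dashed line for 3663254. The 3 labelled pairs of the second table, at 464 to 633 shared sequences, lie far above both lines.

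The same 31053 gene identifiers were listed in all 3 tables, under 31017 distinct symbols. The tables differed in 2 added rows. GFP, the fluorescent protein used to sort the nuclei, was a row of the second table only. saCAS9, named like the Cas9 nuclease of Staphylococcus aureus, was a row of the knockout table only. Reads of GFP could thus be assigned to it in the second table alone, and reads of saCAS9 in the knockout table alone. Of the identifiers, 31011 (99.9%) were found in GENCODE M21, where 21974 were protein coding, 5459 were lincRNA genes and 2816 were antisense genes. The listed protein coding genes made up 99.8% of those in the annotation.

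A gene's row in a table does not show that the gene was detected in any nucleus. Since 99.8% of annotated protein coding genes were listed, the presence of list members was nearly assured beforehand. Every one of the 172 distinct genes in the fixed lists was present in each table. These included all 14 Purkinje markers, such as Pcp2 (chromosome 8, 3623371 to 3625545, minus strand) and Calb1, which encodes the calcium-binding protein calbindin (chromosome 4, 15881264 to 15908064, plus strand). All 11 genes of the Aldoc-positive and all 8 of the Plcb4-positive Purkinje list were present. Aldoc, the aldolase known as zebrin II that marks alternating Purkinje stripes, lies on chromosome 11 (78322968 to 78327781, plus strand). Plcb4, a phospholipase enriched in the complementary stripes, lies on chromosome 2 (135659011 to 136014593, plus strand). The 20 immediate early genes, among them Fos and Arc, the 19 genes of fibroblast growth factor receptor signalling and the 24 genes of parallel fibre plasticity were present as well. Among the plasticity genes, Pick1 was listed under 2 identifiers whose spans on chromosome 15 overlap (79229173 to 79249484 and 79229391 to 79256674). The lists for other cerebellar cells were complete too, from granule cells (10 genes, such as Gabra6) to oligodendrocytes (8 genes, such as Mbp) and microglia (8 genes, such as Cx3cr1).

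Fgfr2, the target of the knockout, was listed once, as ENSMUSG00000030849. In GENCODE M21 the gene spans chromosome 7 from 130162451 to 133123350 on the minus strand of GRCm38, or 2961 kb. That span is set by the longest of its 27 transcripts, while the other 26 span 104 kb. The level of Fgfr2 in knockout and scramble nuclei was not analysed here.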

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

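Of 227 recomputed values, 215 kept their call or stayed within 1.5 times the reported value. Most of the 227 only left 1 library out of the pool, and a ratio counted as kept when its pair stayed above chance. The tally therefore says little of how stable the ratios are. The other 12 values were all counts of pairs below chance. Within tables that count was 1 as reported, 25 with the pool estimated within each table, 0 with the pool estimated without the called pairs, and 0 to 2 with each library in turn left out of the pool. It fell to 0 without library 3, 4 or 5 of the second table and rose to 2 without library 1, 3 or 4 of the knockout table. Across tables it was 1 as reported, 0 with the pool estimated without the called pairs, and 0 to 1 with each library left out, again 0 without library 3, 4 or 5 of the second table. The low calls follow from the construction of the estimate, since the 3 pairs above chance shrink the estimated pool and so raise the expectation for all others. The 3 pairs above chance were called under every alternative, with ratios between 7.11 and 24.0 for libraries 3 and 4, between 4.31 and 14.5 for libraries 3 and 5, and between 7.43 and 25.0 for libraries 4 and 5. Counting only sequences found in 1 library of a table lowered the nuclei of libraries 3, 4 and 5 of the second table by 7.07%, 10.8% and 7.65%. In the 20 other libraries the fall was 1.62% to 2.28%. Matching reverse complements changed no value, and no barcode had a neighbour at 1 base in its library, so both of those settings moved nothing and bear on no result. Alternative settings for cell types and for expression between conditions, fixed before the data were examined, were not run, since no expression values were analysed here. No paired analysis was possible because no library is tied to a sample. The barcode lists carry no read depth, so what depth limits was not assessed.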

Other observations

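The test on sequences found in the other libraries and the test on sequences found in all 3 libraries were set before their results were seen; the other tests here, and the look at the Fgfr2 annotation, were chosen afterwards. No biological explanation was tested, since no library is tied to a condition.

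The pattern is the excess of shared barcode sequences among libraries 3, 4 and 5 of the second table. Sequences favoured in every library do not account for it, because the 874 shared sequences were found in the other 20 libraries at 0.753 times the rate of the 28172 unshared ones (95% interval 0.534 to 1.03). Exchange among all libraries of that table is argued against by the 15 pairs that join one of the 3 libraries to another library of the table, which shared 386 sequences against 380 expected from the pool estimated without the 3 pairs above chance, a ratio of 1.02 (0.916 to 1.12). With the pool from all pairs 462 were expected, a ratio of 0.836 (0.755 to 0.924). A single library listed under 3 numbers is argued against because 9.59% of the smallest library's sequences were found in either of the others. The sequences found in all 3 libraries numbered 425, against 33.2 from independent sharing of each pair. That expectation is the mean of 3 values, with each library in turn as the reference. The ratio was 12.8 (95% interval 11.6 to 14.1), an interval that leaves out the spread of those values. Exchange of molecules between these 3 libraries alone is therefore a candidate explanation. That it came mostly from the same nuclei is not shown, since 449 of the 874 shared sequences were in exactly 2 libraries. The ratio does not single out exchange, because the other 20 libraries cannot show sequences favoured in these 3 alone. Whether exchange happened at all, and if so at library preparation or at sequencing, stays open without transcript counts. So does the library each nucleus came from.

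The first table held 9 libraries for 8 samples. A library of these tables listed under a second number is argued against, since the highest share of a smaller library's sequences found in another, over pairs with a library of the first table, was 0.581% (95% interval 0.458 to 0.726). No label says how many libraries each sample gave, so whether any of the 9 libraries is additional, and which, was not determined.

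The annotated span of Fgfr2 rests on 1 of its 27 transcripts. That transcript, which has support level 5, reaches up to position 133123350 on chromosome 7, while the other 26 reach no higher than 130266263. The lowest position of the other 26, 130162451, is also that of the gene. Fgfr2 lies on the minus strand, so the part that the longest transcript adds lies upstream of the other 26. Without the longest transcript the gene spans 104 kb rather than 2961 kb, a ratio of 28.5. The median ratio was 1.04 over the 19750 listed genes with more than 1 transcript, and 141 of those genes (0.714%) had a ratio at least as large. The added stretch of 2857 kb contains 45 other listed genes, of which 20 lie on the strand of Fgfr2 and 13 of these are protein coding. They include Ate1, an arginyltransferase gene, and Oat, the ornithine aminotransferase gene, both named after their positions were seen. How reads over this stretch were assigned was not analysed here, and the use of intronic reads, which are abundant in nuclei, is not given in the sources used here.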
